A study of Homo sapiens and Mus musculus with 23 samples.

How the data were processed

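Chromatin immunoprecipitation sequencing was performed on K562 cells and on mouse MLL-AF9 leukaemia cells. The labels assign 23 samples to 21 groups by cell type, guide or compound, and antibody, and guides against the same target were kept as separate groups. The analysis started from 3 peak lists without headers. The lists for FLAG-MLL-AF9 and H3K79me2 match 1 sample each by name. The H3K4me3 list matches the K562 control-guide group, which has 2 samples, without showing which of them it came from. Its name carries an abbreviation that the labels do not spell out, read here as the control guide because it names no knocked-out gene and the control guide is the only H3K4me3 group without one. The cell type of 4 K562 samples is written with rising numbers in the labels and was read as K562.

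Reads were processed with bcl2fastq, cutadapt, BWA and SAMtools and peaks were called with MACS2, per the submitters' processing notes, which give no versions here and name the builds GRCh37 and mm10. The last H3K4me3 peak on chromosome 1 ended at 249220077, which is 282978 bp beyond the last gene end in the GRCh38 gene table at hand. Whether samples were pooled, whether a control library was used and how duplicates were handled are not given in the sources used here. The deposited fold enrichment is the ratio of the signal to the caller's background, at the summit for FLAG-MLL-AF9 and averaged over the region for the broad lists, per the format of the authors' files. The deposited significance is -log10 of a q-value, and for FLAG-MLL-AF9 the -log10 of the p-value at the summit was read too. These per-peak values are the authors' own and were used only to describe, rank and filter peaks within a list. A call depends on depth, background and threshold, so a place without a peak is not a place without signal. The lowest -log10 q was 1.36 for FLAG-MLL-AF9, 1.02 for H3K79me2 and 1.01 for H3K4me3.

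Overlaps of at least 1 bp were counted with bedtools 2.31.1. Other values were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Shares carry exact Clopper-Pearson 95% intervals and medians 95% bootstrap intervals over regions from 1000 resamples. Both cover the regions counted and not replicate error. They treat peaks or domains as independent, although neighbours on a chromosome are not. Random overlap came from 1000 placements in which the FLAG-MLL-AF9 peaks of a chromosome were shifted together, around its covered span. Distances used 200 placements, and the number of clusters 100 uniform draws. Peaks of FLAG-MLL-AF9 up to 10 kb apart formed a region. The code was tested on simulated data. It recovered 1505 of 1505 peaks put on a domain, 2258 of 2258 put off all domains and 3000 of 3000 simulated summit counts.

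Summit fragments were recovered after the lists had been seen. Fold was taken as summit fragments plus 1 over background plus 1, and p as the Poisson tail, which is how MACS2 builds these columns. A whole number of fragments solved both for all 3763 peaks, with a largest mismatch of 0.00016 in -log10 p, where 1 fragment changes it by at least 0.056. With the smallest peak width, 271 bp, taken as the fragment length, the background of 3689 peaks equalled a whole number of fragments in 10 kb within 0.02, and the other 74 shared the lowest value. Intervals on these counts are exact Poisson intervals. Fragments are not independent molecules, so they cover counting error only.

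Before the data were examined, the comparisons, the alternatives and the rule for named regions were fixed. The rule took the 10 highest-fold FLAG-MLL-AF9 peaks, 1 per 10 kb region, the 10 widest H3K79me2 domains and the 10 widest H3K4me3 peaks. It also took the genes with the 10 largest totals of FLAG-covered bases. Without gene positions, these genes were replaced by the 10 regions of joined peaks with the most FLAG-covered bases. That replacement was not part of the fixed rule. Lists of genes had been fixed too, but the gene table at hand was for GRCh38 and an annotation of GRCh37 or mm10 was not used here, so gene names, distances to promoters and the gene lists were left out. Alternatives changed the overlap rule, the -log10 q minimum of 5, the fold minimum, the joining of domains over 3 kb or of H3K4me3 peaks over 1 kb, the chromosomes and the random placement. The summit counts, the 100 strongest peaks, clusters and the position profile were chosen after the lists had been seen.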

Results

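The series comprised 23 chromatin immunoprecipitation sequencing libraries in 21 groups, 13 from K562, a human chronic myeloid leukaemia cell line, and 10 from mouse acute myeloid leukaemia cells driven by MLL-AF9, a fusion of the histone methyltransferase MLL with AF9. The libraries profiled RNA polymerase II, the promoter mark H3K4me3, the acetylation mark H3K27ac, the transcribed-gene mark H3K79me2 and the FLAG-tagged fusion protein itself. Knockout guides, a menin inhibitor and a DOT1L inhibitor were set against control guides or the solvent DMSO. Peak lists of 3 control groups were analysed here: FLAG-MLL-AF9 after 48 hours of DMSO, H3K79me2 after 72 hours of DMSO, and H3K4me3 in K562 cells 6 days after a control guide. The knockout, inhibitor, polymerase II and H3K27ac arms were not analysed here, so no value below measures an effect of a knockout or inhibitor. Each group entered with 1 peak list, without replicates, and no p-value is given. Intervals describe the regions of a list and do not measure variation between cultures. An annotation of the builds in use was not used here, so regions are named by position, in mm10 for mouse and GRCh37 for human.

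The FLAG-MLL-AF9 list held 3763 narrow peaks covering 1.65 Mb, with a median width of 369 bp (95% bootstrap interval 363 to 375). Their median fold enrichment was 5.02, between 1.72 and 21.2. The H3K79me2 list held 10234 broader domains over 14.1 Mb, with a median width of 1208 bp (interval 1189 to 1228) and a median fold enrichment of 2.84. The widest domain reached 7350 bp. The H3K4me3 list of K562 held 23838 peaks over 25.9 Mb, with a median width of 984 bp (interval 972 to 997) and a median fold enrichment of 4.31. Fold values were compared only within a list. The depth of the H3K79me2 and H3K4me3 libraries is unknown from these lists. For FLAG-MLL-AF9, fold and -log10 p together fixed the number of fragments at each summit, with a median of 16 and a range of 7 to 184. The lowest background in that list corresponded to 37.1 fragments per 10 kb, or 3710 per megabase.

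The first comparison asked how far the fusion protein and H3K79me2, the mark laid down by DOT1L, occupied the same places in the same cells. Of the FLAG-MLL-AF9 peaks, 1440 of 3763 overlapped an H3K79me2 domain by at least 1 bp, a share of 38.3% (exact Clopper-Pearson 95% interval 36.7 to 39.8). Peaks shifted at random along their own chromosome met a domain in 0.780% of cases on average over 1000 placements, and the highest placement reached 2.82%. The observed share was 49.0 times the random mean. Placements ran over the whole covered span of a chromosome and were not matched to genes or open chromatin. Lists that only share a preference for such places would also exceed them, so neither this ratio nor the distances below measure an overlap specific to the fusion protein. A domain lay within 1 kb of 61.5% of the peaks (interval 59.9 to 63.0), against a mean of 1.64% over 200 random placements. Within 5 kb the share was 68.3%, against 4.63%. Counted from the other side, 1406 of the 10234 domains held a FLAG-MLL-AF9 peak, or 13.7% (interval 13.1 to 14.4), so most H3K79me2 domains had no called fusion peak. When a summit had to lie inside a domain, the shares were 22.2% of peaks and 7.93% of domains, and with 50% of the peak covered they were 22.6% and 8.09%. With FLAG peaks of -log10 q of at least 5 only, 7.93% of domains held a peak, and with those at or above the median fold 7.13%. With domains of -log10 q of at least 5 only, 9.73% of peaks met a domain.

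The overlap rose with the number of fragments at the FLAG-MLL-AF9 summit and with peak width, and differed little between groups of fold enrichment. The peaks were split into 4 groups of equal size. In the group with the fewest summit fragments, 7 to 13, 26.0% of peaks overlapped a domain (interval 23.3 to 29.0). In the group with the most, 20 to 184, the share was 47.6% (interval 44.4 to 50.9). Across 4 groups ranked by fold enrichment the share stayed between 37.4% and 39.0%, within the intervals of each other, although among the 50 highest-fold peaks it was 24.0% (interval 13.1 to 38.2). By width it rose from 22.6% in the narrowest group to 59.1% in the widest, and a wide peak meets a domain more easily. The 100 peaks with the most summit fragments overlapped a domain in 33.0% of cases (interval 23.9 to 43.1), and the other peaks in 38.4%. A domain lay within 1 kb of 53.0% of these 100 strongest peaks (interval 42.8 to 63.1) and of 61.7% of the others (interval 60.1 to 63.3). Within 5 kb of the strongest a domain was called in 92.0% of cases (interval 84.8 to 96.5), against 67.7% (interval 66.2 to 69.2) for the others. Some of the 100 strongest lay close together and shared domains, among them all 8 peaks of a cluster at 6:52216985-52234770. Intervals for these 100 are therefore too narrow.

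Apart from the 100 strongest, FLAG-MLL-AF9 summits lay inside a domain less often than positions 750 bp to either side. Of these 3663 summits, 22.3% lay inside a domain (interval 20.96 to 23.7). At 750 bp on either side the share rose to 26.3% and 27.7%, while it averaged 14.7% at 1 to 3 kb and 2.01% at 9 to 10 kb. Around the 100 strongest summits the share was 18.0% at the summit (interval 11.0 to 26.9), averaged 20.3% at 1 to 3 kb and was still 8.50% at 9 to 10 kb.

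**Figure D1:**
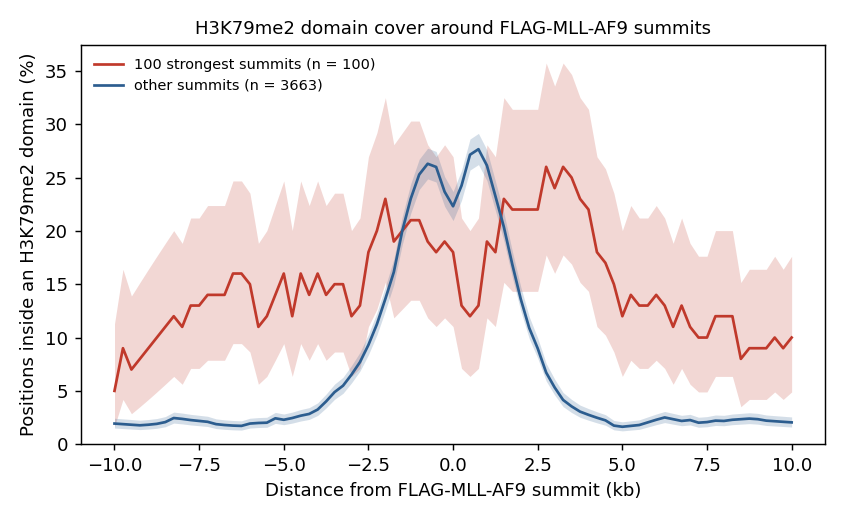
Share of positions inside an H3K79me2 domain (y axis, percent) against the distance from the FLAG-MLL-AF9 summit (x axis, kb), for the 100 summits with the most fragments (red) and the 3663 others (blue); shading gives exact 95% binomial intervals. The others fall to 22.3% at the summit between shoulders of 26.3% and 27.7%, while the strongest summits keep 8.50% at 9 to 10 kb.

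Domains that held a FLAG-MLL-AF9 peak were wider than those that did not. Their median width was 1782 bp against 1135 bp, a difference of 646.5 bp (bootstrap interval 584 to 708), which was 301.5 bp among domains of -log10 q of at least 5. The share of domains with a peak rose from 3.71% in the narrowest 10% of domains to 33.2% in the widest 10%. A wide domain is met more easily by chance. Domains met by randomly shifted peaks had a median width of 1597 bp, 184.5 bp below that of the domains with a peak. The median fold enrichment was 2.72 in domains with a peak and 2.86 in those without (difference -0.15, interval -0.20 to -0.10). The difference was -0.32 with domains of -log10 q of at least 5, -0.25 with FLAG peaks of -log10 q of at least 5 and -0.23 with domains joined over 3 kb. Within 10 classes of domain width the sign depended on the width. Domains with a peak had the higher fold in the 5 narrower classes, by 0.017 to 0.48, which held 326 of the 1406, and the lower fold in the 5 wider classes, with differences from -0.18 to -0.024. The plain mean over classes was 0.086, and weighted by domains with a peak it was 0.010. The median -log10 q went the other way, 3.60 in domains with a peak and 2.61 in those without (difference 0.99, interval 0.87 to 1.12). It also rose with domain width (rank correlation 0.41).

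Among the 10 widest H3K79me2 domains, 4 held a FLAG-MLL-AF9 peak. The widest lay at 1:80330195-80337544 and held none. The next, at 19:37376493-37383577, spanned 7085 bp and held 1 peak, as did 8:126586640-126592998, with 6359 bp. A domain of 6185 bp at 5:52183656-52189840 held none, nor did 3:27703740-27709573, with 5834 bp. The fold enrichment of these 10 domains was low, between 1.71 and 2.04, against the list median of 2.84. Of the 100 widest domains, 45 held a peak (interval 35.0 to 55.3).

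Some called FLAG-MLL-AF9 peaks lay in clusters. Peaks up to 10 kb apart were joined into 3425 regions, of which 37 held 3 or more peaks. Uniform random placement gave a mean of 0.940 such regions over 100 draws and at most 5. Any list gathered in part of the genome would exceed uniform placement, so this does not show clustering particular to the fusion protein. Whether the caller divided 1 bound stretch into several peaks was not tested. A domain was called inside 34 of the 37 regions, or 91.9% (interval 78.1 to 98.3), against 38.0% (interval 36.3 to 39.7) of the 3142 regions with a single peak, which are much shorter. Within 10 kb of the region, the shares were 100% (interval 90.5 to 100) and 66.6% (interval 64.9 to 68.2). Peaks of the clusters had a median of 48 summit fragments and a median fold of 3.56, while single peaks had 15 fragments and a fold of 5.12.

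The 10 regions with the most FLAG-covered bases held 2359 to 3726 bp of peaks each, in 2 to 8 peaks, with 87 to 184 fragments at their highest summits, and 9 of the 10 contained an H3K79me2 domain. The first was 12:73039140-73053161, with 3 peaks and 101 fragments at its highest summit (exact Poisson 95% interval 82.3 to 122.7, counting error only). Next came 3:58414651-58434832, with 3 peaks, 170 fragments (interval 145.4 to 197.6) and 5 domains that covered 41.7% of it. The region 6:52216985-52234770 held the most peaks of any, 8, and 2 domains that covered 18.1% of it. At 4:58894538-58913081, 5 peaks reached 177 fragments (interval 151.9 to 205.1) and 4 domains covered 32.6%. Smaller totals were found at 12:76361816-76371654, 7:73541400-73558635, 3:35923646-35933841, 11:19007476-19019109 and 4:28813110-28815948. The highest summit of the list, 184 fragments (interval 158.4 to 212.6), lay at 13:103919239-103921963, the region of these 10 without a domain inside, although 1 was called within 10 kb.

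The region on chromosome 6 had the most fragments in a 10 kb background window, 2320, against a list median of 82. Its 8 peaks had 94 to 124 summit fragments and yet fold enrichments of only 1.72 to 2.58. Of the 10 lowest fold values in the list, 7 lay in this region and 9 in regions of 3 or more peaks.

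**Figure D2:**
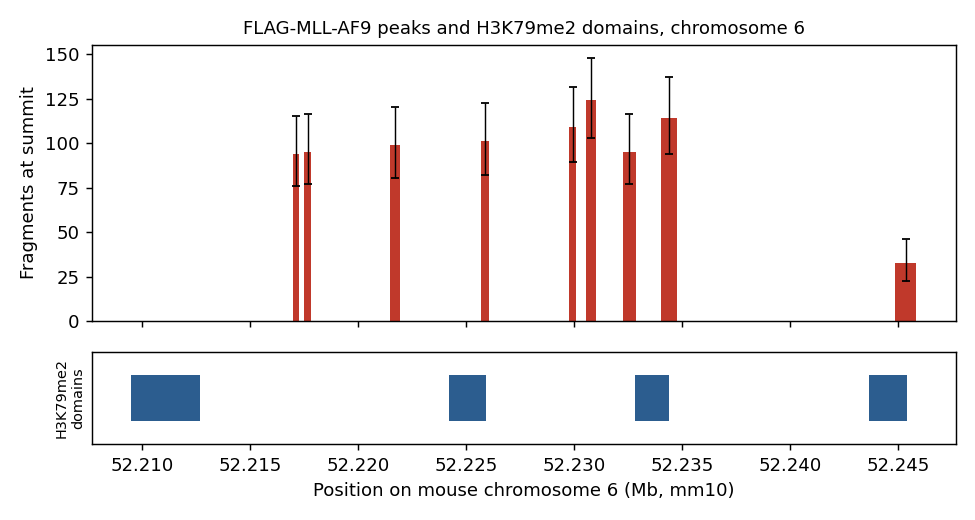
Map of the FLAG-MLL-AF9 cluster on mouse chromosome 6 (x axis, position in Mb, mm10). Red bars mark each FLAG peak at its position and width, with its summit fragments as height and exact Poisson 95% intervals; blue boxes mark H3K79me2 domains. The 8 peaks of the cluster reach 94 to 124 fragments, and the separate peak to the right reaches 33.

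**Figure D3:**
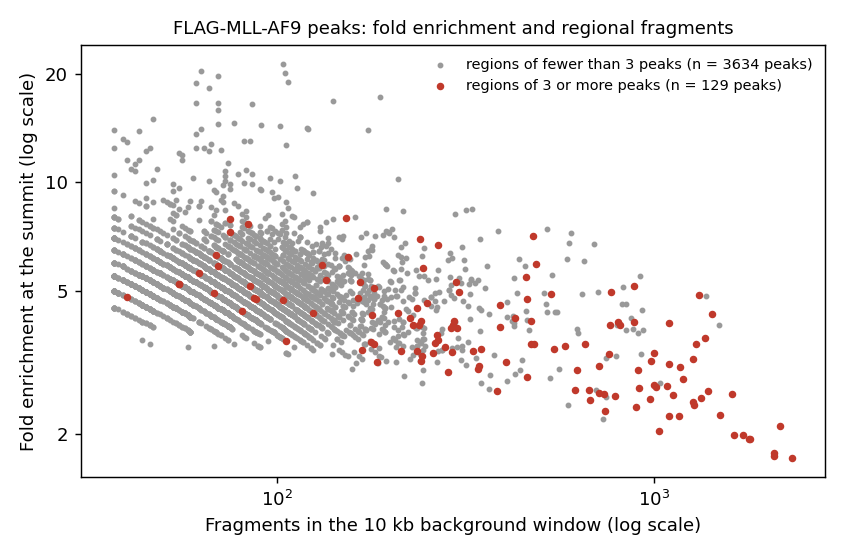
Fold enrichment at the summit (y axis, log scale) against fragments in the 10 kb background window (x axis, log scale) for the 3763 FLAG-MLL-AF9 peaks, each a point; red points are the 129 peaks in regions of 3 or more. The region with the most fragments, 2320, lies at the bottom right with a fold of 1.72.

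None of the 50 highest-fold peaks lay in a region of 3 or more peaks, and 49 were the single peak of their region. Of all 3763 peaks, 129 lay in regions of 3 or more and 3142 were single. Few of any 50 peaks would thus lie in a cluster. The highest fold was at X:143482819-143483313, with 21.2 and 80 summit fragments (interval 63.4 to 99.6), followed by 16:98107293-98107601 at 20.3 and 17:67741219-67741663 at 20.0. Each of these lay on a short H3K79me2 domain of nearly the same position, with domain folds of 12.8, 8.72 and 9.97. The peaks 18:40308106-40308590, with a fold of 18.3, and 17:36231183-36231811, with 17.2, did so too. What gives calls at nearly the same position in both lists was not tested. These positions are therefore not shown to be strong sites of the fusion protein or of the mark. No domain was called under the other 5 of the 10, at 14:124801512-124801900, 2:33018014-33018468, 17:62737338-62737842, 9:21950281-21950766 and 15:72568509-72568959, whose folds ran from 16.6 to 19.7.

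In K562, the H3K4me3 list described the mark in control cells. H3K4me3 was also profiled after guides for the polymerase subunit Rpb1 and for RBBP5, a subunit of the H3K4 methyltransferase complexes. None of the 3 peak lists came from these knockout groups, so the control list is not set against either. Which of the 2 control-guide samples gave it is not known. Peak width had quartiles of 538 and 1494 bp, and fold enrichment quartiles of 3.48 and 5.41. Fold rose with width up to peaks of 1166 to 1374 bp, where its median was 5.61, and fell to 3.83 in the widest 10% of peaks, against 3.62 in the narrowest 10%. Across peaks, which are not independent replicates, Spearman's rank correlation of width and fold was 0.21 (bootstrap interval 0.20 to 0.22). Among the 13911 peaks of -log10 q of at least 5 it was -0.63. That minimum also selects by width, since -log10 q rose with width (rank correlation 0.62). Its median was 2.22 in the narrowest 10% of peaks and 16.7 in the widest 10%. The value of -0.63 therefore describes the selected peaks only.

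**Figure D4:**
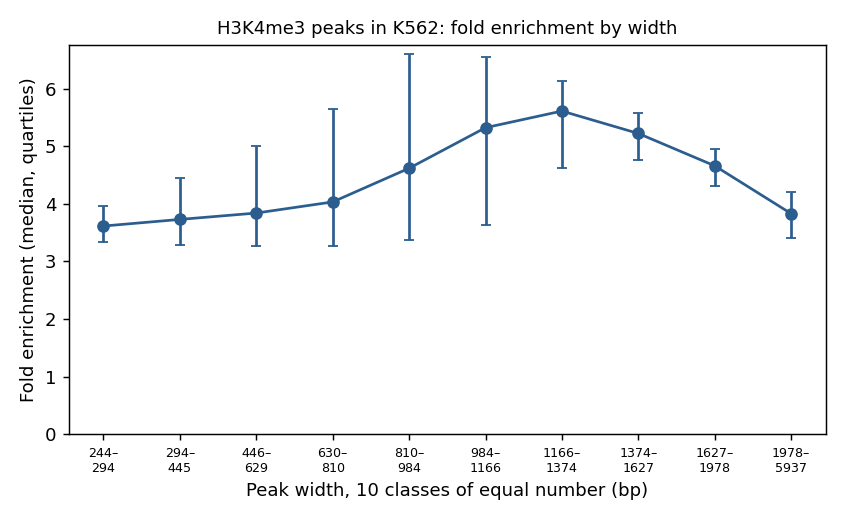
Fold enrichment of H3K4me3 peaks in K562 control cells (y axis, median as points, quartiles as bars) in 10 classes of peak width (x axis, width range in bp). The median rises from 3.62 to 5.61 at 1166 to 1374 bp and falls to 3.83 in the widest class.

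The 5% broadest H3K4me3 peaks, 1192 peaks from 2317 bp upwards, held 12.9% of the covered bases. Their median fold was 3.49, against 4.40 in the others, and their median -log10 q was 14.9, against 7.25. The widest peak lay at 6:37137061-37142997, with 5937 bp and a fold of 2.17. It was followed by 6:68593585-68599029 with 5445 bp, 5:180614389-180619539 with 5151 bp, 16:85586788-85591909 with 5122 bp and 19:13260581-13265636 with 5056 bp. The remaining peaks among the 10 widest lay at 6:30650580-30655624, 15:37389962-37394849, 18:3447702-3452455, 1:145437694-145442425 and 6:15244871-15249503. Their folds ran from 1.85 to 3.01, and 4 of the 10 were on chromosome 6, which held 7.38% of all peaks and 11 of the 100 widest.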

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

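The choices by summit fragments, by fold of 10 or more, by a distance of 1 kb, by weighting and against randomly met domains were made after seeing the data; the others were planned. Under uniform placement the overlap was 49.4 times the random mean; random placement was not repeated under the other choices. Leaving out each of the 20 chromosomes gave 37.8% to 38.7% of FLAG-MLL-AF9 peaks and 13.5% to 14.0% of domains. The share of peaks on a domain was 22.2% with the summit inside, 22.6% with 50% of the peak covered, 41.7% with FLAG -log10 q of at least 5, 9.73% with domain -log10 q of at least 5 (1741 domains left), 45.9% for summit fragments at or above their median, 33.0% for the 100 strongest peaks and 61.5% within 1 kb. The share of domains with a peak was 7.93% with the summit inside, 8.09% with 50% covered, 7.93% with FLAG -log10 q of at least 5 (1981 peaks left), 20.4% with domain -log10 q of at least 5, 7.13% at or above the median FLAG fold and 14.8% with domains joined. The width difference was 301.5 bp with domain -log10 q of at least 5 and 184.5 bp against domains met at random. The fold difference was -0.25 with stricter FLAG peaks, -0.32 with stricter domains and -0.23 with joined domains. Within 10 classes of domain width its mean was 0.086, or 0.010 weighted by domains with a peak, positive in the 5 narrower classes and negative in the 5 wider; the cause was not tested. With H3K4me3 -log10 q of at least 5, the median width was 1350 bp, the median fold 5.20 and the rank correlation of width and fold -0.63, of opposite sign, with 13911 peaks left; its cause was not tested. The other 58 of 81 values stayed within the interval of the value reported, while 20 left it and 3 changed sign. The 58 include every value with 1 of the 20 chromosomes left out, for both shares. Leaving out 1 chromosome removes few peaks and could hardly move a share. The count of 58 is therefore no measure of how stable the results are. Alternatives that need gene positions were not run. Depth may limit the shares, since a weak domain can be missed, but its effect was not tested.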

Other observations

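In the H3K79me2 list, marked stretches also appeared as series of separate domains. Chosen after the values were seen, the stretch with the most covered bases after joining over 3 kb lay at 3:103914838-103931962, where 4 domains covered 10364 bp and 1 FLAG-MLL-AF9 peak was called. At 3:58426413-58440276, 5 domains covered 8215 bp with 2 peaks. The stretch 6:17637647-17647185 held 7686 bp in 2 domains and 19:12779659-12793215 held 7468 bp in 4, both without a called fusion peak, while the other 8 of the 10 stretches with the most covered bases held at least 1. Of the 10 highest-fold domains, 9 held a FLAG-MLL-AF9 peak, against 13.7% of all domains. The exception lay at 8:20295823-20297299, with a fold of 6.72. These 9 were short, 294 to 927 bp, against a list median of 1208 bp. They included the 5 domains that lay at nearly the same position as a highest-fold FLAG-MLL-AF9 peak. What gives such calls was not tested, so the 9 are not shown to be strong sites of the mark or of the fusion protein. Over all domains, those with a peak had the lower median fold, 2.72 against 2.86.

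In K562, among chromosomes 1 to 22 and X, H3K4me3 peaks were densest on chromosome 19, with 25.1 per Mb, then on chromosome 17, with 15.5, and sparsest on the X chromosome, with 3.92. Chosen after the values were seen, the longest stretches without a peak, 1 per chromosome, were 1:121329208-142618493, 9:46113152-66457651, 16:33616133-46588249 and X:89714353-99986064. Whether reads can be placed in these stretches was not tested, so they are not shown to lack the mark. The 10 highest-fold peaks were short, 303 to 618 bp, with folds from 11.2 to 12.7. The first lay at 7:102212689-102213129.

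Of the 50 highest-fold FLAG-MLL-AF9 peaks, 12 met an H3K79me2 domain, or 24.0% (interval 13.1 to 38.2), against 38.3% of all peaks, and these 12 domains had a median width of 492.5 bp and a median fold of 6.88, against 1793.5 bp and 2.71 for the other domains with a peak. Peak and domain shared a median of 91.4% of the bases that either covered, against 12.8% for other FLAG-MLL-AF9 peaks on a domain. The cause was not tested.

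The tests below on clustered FLAG-MLL-AF9 peaks were chosen after their results were seen. The pattern at the strongest summits was also found in the data, and its tests were fixed after that but before the values they measure were seen. No biological explanation that sets groups of the design against each other was tested for either pattern, since the inhibitor and knockout arms were not analysed here.

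Clustered FLAG-MLL-AF9 peaks had low fold, 3.56 against 5.12 for single peaks. The tables argue against few fragments at these summits, whose median count was 3.20 times that of single peaks. They also argue against a control library with 1 kb windows, since 7.75% of the clustered backgrounds were multiples of 10 window counts (interval 3.78 to 13.8), close to the 10% that chance gives. A control library scaled to another depth is argued against too. All 3689 backgrounds above the lowest value were whole fragment counts in 10 kb, within 0.02. A background counted in the same library may account for the low folds. The lowest background, shared by 74 peaks, was 37.1 fragments per 10 kb, which is not a whole count. Of the 221 peaks with more summit fragments than that, none had fewer fragments in the 10 kb window than at the summit. That is 0.0% (upper limit 1.66%), where windows drawn from the weaker peaks would give 32.4%. The windows behind the 32.4% were drawn without regard to summit counts, so that value cannot exclude a control whose counts rise with the summits. With a background from the same library, fold would understate dense fusion-bound regions. Not all ranked last. The best peak of 7:73541400-73558635, a region of 4 peaks, ranked 249 of 3763 by fold, with 7.11. That of 13:103919239-103921963, which holds only 2 peaks, ranked 2193. Whether weaker peaks beside dense regions were missed stays open.

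The 100 strongest FLAG-MLL-AF9 summits often lay beside and not inside a called domain. Splitting of domains by the caller over gaps of up to 3 kb is argued against, because joining over 3 kb put only 34.0% of these peaks on a domain, against 33.0% before. Splitting over wider gaps was not tested. Such a gap ran from 52212664 to 52224231 at the chromosome 6 cluster. A lower share of called H3K79me2 at the summit cannot be told apart from an even share at this number of summits, with 18.0% at the summit (interval 11.0 to 26.9) against 20.3% at 1 to 3 kb. Marked stretches that raise their own background may contribute, since domains within 10 kb of these summits had a median fold of 1.91 against 2.59 near the others, a difference of -0.68 (interval -0.74 to -0.63). Truly weaker H3K79me2 around these summits would give the same value and stays open.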
